A study of Mus musculus with 9 samples.

How the data were processed

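RNA from mouse gastrocnemius, the large calf muscle, was measured in 3 groups of 3 libraries: wildtype mice given vehicle, mdx mice given vehicle, and mdx mice given GTx-026 at 10 mg/kg under the skin. The mdx mouse carries a mutation in the dystrophin gene Dmd and is a model of Duchenne muscular dystrophy, and GTx-026 is the drug under study. Per the labels' protocols, polyadenylated RNA was selected from total RNA, made into barcoded libraries and sequenced on an Ion Torrent Proton. The labels give 3 animals to a group but tie no library to an animal, so the p-values measure the spread between these libraries. That spread was pooled over the 3 groups, so the p-values of a comparison rest also on the group outside it. All libraries, mdx included, carry the strain label C57BL/6. The columns of the deposited table name the group and a number, so each column was assigned to its group only, and a library's number is a name that pairs nothing.

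Per the submitters' processing notes, TopHat2 2.0.13, Bowtie2 2.2.4, SAMtools 0.1.19, HTSeq 0.6.1p1, DESeq2 1.6.3 and the genome build GRCm38.p3 were used, with neither role nor order given; the gene annotation and any use of strand were not given in the sources used here. The deposited signal of each library is a scaled read number for every sequence record, 46442 records in all. In each library all values below 10000 lay within 0.1 read of a whole multiple of a single step, so the authors' signal was read as reads multiplied by 1 factor per library, and the listed reads were estimated by dividing by that step. The smallest signal above 0 was 10, and a record at 0 in 1 library was at 0 in all 3 libraries of that group, which was the case for 431 records in at least 1 group. Low values may thus have been set to 0 group by group, a rule not given in the sources used here, so a value of 0 is read as listed at 0, not as absence of reads. Per the file headers the table also holds the authors' group means, the authors' ratio of those means, and the authors' deposited p-value for each pair of groups. On 2000 records these p-values and ratios were recomputed from the scaled signal with a largest difference of 5e-11, and the p-values are not adjusted for multiple tests. All columns of per-sample values were used.

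Records were summed by gene symbol. Of the tested symbols 9006 had more than 1 record. A read counted for several records would enter the sum of its gene, and the estimated listed reads, more than once. The 4 records without a symbol held 0.000646% of the deposited total and were left out. A gene was tested when at least 1 of its records was above 0 in all 9 libraries, and only such records entered its sum, which gave 15372 tested genes of 15593 symbols and 99.98% of the deposited total. The 221 other symbols entered no test. The choices fixed before the data were examined were the groups, the tests, the gene lists, the rule for named genes and the alternative settings listed first below, including the fallback for scaled values that was used here. The first choice in that plan was a count-model test. It was not run, because the table holds scaled values. Values below 10000 lay near whole multiples of the step, but reads recovered in this way were not accepted as counts. The count-model alternatives of the plan were not run for the same reason.

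Libraries were rescaled by a trimmed mean of log ratios, unweighted, with 30% trimmed on the ratio and 5% on the level, which gave factors of 0.874 to 1.30. Values are printed as CPM, a gene's reads for every M (mega) reads of its library after rescaling, as mean ± SD with n = 3. Only the values of genes listed at 0 in a whole group are printed without this rescaling. Tests used limma 3.58.1 in R 4.3.3 with a trended prior variance on log2(value + 1), with all 9 libraries in a single model, 6 residual degrees of freedom and 3.61 prior degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested genes within a comparison, with a threshold of 0.05. Log2 fold changes are on the log2(value + 1) scale, which understates the change of low genes, and are given with the model's standard error (SE). The estimated listed reads per library ran from 25.1 M to 38.0 M. At this depth 1 CPM corresponds to more than 25 reads per library.

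Of 37 gene lists fixed in advance, 34 had the minimum of 3 measured members and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. The same lists were tested with a correlation estimated for each list and with fry. Members past the threshold were counted over all genes and after adjustment over the list alone. The named genes were Dmd whatever its values; in each of the first 2 comparisons up to 8 genes with the largest rise and up to 8 with the largest fall among those past the threshold, at 5 CPM or more on average and with no overlap between the groups; and the members of each list with the smallest p. In mdx GTx-026 against wildtype vehicle the rule took 3 rises and 3 falls. Predicted symbols were passed over by the rule, and those printed were chosen after their values were seen. Of the genes fixed in advance, 1 is not reported here.

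Reversal of mdx changes was examined with covariances and correlations of log2 fold changes, beside 100 simulations of unchanged groups sharing the same libraries. Gene positions were taken from the RefSeq table of GRCm38.p6, which has the same primary assembly as GRCm38.p3. Sharing of sequence with other genes was checked as the percent of a gene's 50-base words found in transcripts of another gene of the GENCODE vM21 set; of 290 genes looked up, 267 had transcripts there and 24 shared at least 10% with another gene. The programs were tested on simulated data with the real genes' means and spread, 200 of 15372 genes being changed. The simulated noise was independent between genes and alike in all groups, which the real libraries are not. The rates that follow therefore test the programs and do not give the error rate of the real calls. For mdx vehicle against wildtype vehicle, mdx GTx-026 against mdx vehicle and mdx GTx-026 against wildtype vehicle, 29%, 38% and 35% of 2-fold changes and 80%, 89% and 86% of 4-fold changes were recovered, with 5 wrong calls in each among 114, 132 and 126 calls.

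The alternatives were 2 other scalings, pseudocounts of 0.5 and 5, no filter, a filter of 5 CPM in 3 libraries, a model of the compared groups only, other thresholds and leaving out each library in turn. Array quality weights, the highest record in place of the sum, and observation weights from the mean-variance trend were added after seeing the data. GC content and gene length were not tested, and a paired model was not possible.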

Results

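The study asked, by its title, what a class of drugs does in models of Duchenne muscular dystrophy. Polyadenylated RNA of gastrocnemius muscle was sequenced from wildtype mice given vehicle, mdx mice given vehicle and mdx mice given GTx-026, a drug of that class, with 3 libraries in each group. The estimated reads listed in the table were 28.1 M, 33.5 M and 30.3 M in the wildtype vehicle libraries 1 to 3. They were 25.1 M, 35.9 M and 31.8 M in the mdx vehicle libraries and 38.0 M, 29.3 M and 34.0 M in the mdx GTx-026 libraries. The 10 most abundant genes took 19.6% to 28.5% of a library. The first principal component held 36% of the variance between libraries and the second 20.7%. The mdx vehicle library 1 stood apart from the rest. Its median correlation with the other libraries of its group, across genes, which are not independent replicates, was 0.941, and those of the other 8 libraries lay between 0.955 and 0.980. In that library the slow-fibre contractile genes, such as the myosins and troponins of slow-twitch muscle, lay at a median log2 difference of −3.05 from the wildtype mean. The 8 others lay between −1.66 and 1.74.

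Dmd (chromosome X, 82814664 to 85205050, GRCm38.p6) is the dystrophin gene mutated in mdx mice. It was listed at 50.8 ± 9.30 CPM in wildtype vehicle, 18.3 ± 5.97 CPM in mdx vehicle and 16.6 ± 2.07 CPM in mdx GTx-026 (SD, n = 3 each). The log2 fold change in mdx vehicle was −1.52 (SE 0.26), just short of the threshold over all genes (limma, Benjamini-Hochberg adjusted p = 0.0519). The groups did not overlap, and Dmd passed when adjusted over the list alone. Leaving out mdx vehicle library 1 or 2 brought the adjusted p of Dmd under the threshold, and over all the alternatives it ran from 0.00966 to 0.25. In mdx GTx-026 Dmd fell by 1.604 on the log2 scale against wildtype vehicle (adjusted p = 0.0191). That call was lost without wildtype vehicle library 2 or 3 or any of the mdx GTx-026 libraries (adjusted p up to 0.094). The mdx mutation is a premature stop in the transcript, so the level of Dmd mRNA is only an indirect check of the labels.

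In mdx vehicle against wildtype vehicle, the comparison of mutant with wildtype muscle, the gene that rose most was that of the metal-binding metallothionein Mt2 (chromosome 8, 94172618 to 94173567). It was at 67.9 ± 38.2 CPM against 2.64 ± 0.653 CPM in wildtype (SD, n = 3; log2 fold change 4.49, SE 0.43, adjusted p = 0.00551). Its neighbour Mt1 (chromosome 8, 94178883 to 94180327) was at 88.7 ± 53.3 against 8.66 ± 1.90 CPM (3.14, adjusted p = 0.0261). Lgals3 (chromosome 14, 47373860 to 47386167), which encodes the macrophage lectin galectin-3, rose from 5.33 ± 2.14 to 110 ± 80.8 CPM (4.05, SE 0.60, adjusted p = 0.0296). Prune2 (chromosome 19, 16955668 to 17223963) rose from 2.95 ± 1.66 to 38.6 ± 12.7 CPM (3.77, SE 0.37, adjusted p = 0.00551). The phosphatase gene Dusp26 (chromosome 8, 31089527 to 31097046) fell most, from 53.8 ± 14.4 to 3.59 ± 2.75 CPM (−4.14, SE 0.55, adjusted p = 0.024). Gcsh (chromosome 8, 116981967 to 116993498), a subunit of the mitochondrial glycine cleavage system, fell from 40.5 ± 3.80 to 5.41 ± 1.86 CPM (−2.96, SE 0.27, adjusted p = 0.00547).

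Among the other genes that rose in mdx vehicle were Igf2 (chromosome 7, 142650768 to 142666816), a fetal growth factor, with a log2 fold change of 2.57, and the lysine methyltransferase gene Mettl21e (2.92). Igfn1 (3.21), the protease inhibitor Serpinb1a (2.52) and the calcium-binding S100a4 (2.14) rose too. Igf2 shared 61.2% of its 50-base words with Gm49394, and S100a4 shared 47.4% with Gm42674, so reads of these genes are uncertain. Genes that fell included Rasd2 (−2.04), Osbpl6 (−1.73), the DNA repair glycosylase Tdg (chromosome 10, 82629814 to 82650799; −1.67) and the calcium channel subunit Cacng7 (−1.59). So did the clock repressor Nr1d1 (chromosome 11, 98767932 to 98775377; −1.29). Nr1d1 was at 155 ± 23.3 CPM in wildtype and 62.7 ± 5.43 CPM in mdx vehicle (SD, n = 3). Gm9855, a transcribed pseudogene of Tdg, rose by 2.17 (SE 0.16, adjusted p = 0.00108). It shared 76.5% of its words with Tdg, and the summed pair differed by −0.25, so neither value is secure. Tdg itself shared only 15.8% of its words with Gm9855. In all, 32 genes rose and 19 fell of 15372 tested (limma with Benjamini-Hochberg adjustment), with log2 fold changes of 1.04 to 4.49 in size. At an unadjusted p under 0.05 there were 1958 genes, and 2530 genes (16.5%) had no overlap between the groups where chance gives 10%.

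The count of 51 genes depended on single libraries. It was 20, 8 and 5 without wildtype vehicle libraries 1, 2 and 3 and 85 and 7 without mdx vehicle libraries 2 and 3. It was 13 and 21 without mdx GTx-026 libraries 2 and 3, which enter this comparison through the pooled spread. In a model of the compared groups only it was 6, of which 5 were among the 51. Gcsh, Mt2 and Prune2 passed without any single library. Over all 19 alternatives Gcsh passed in each, and Mt2 and Prune2 in 18 (highest limma adjusted p = 0.0586 and 0.0613). The other called genes named by the rule lost the call without wildtype vehicle library 2 and without library 3. All of them except Cacng7 lost it also without mdx vehicle library 3. Their highest adjusted p lay between 0.101 for Nr1d1 and 0.233 for Igfn1. S100a4 and Gm9855, which the rule did not name, were not examined in this way.

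**Figure D1:**
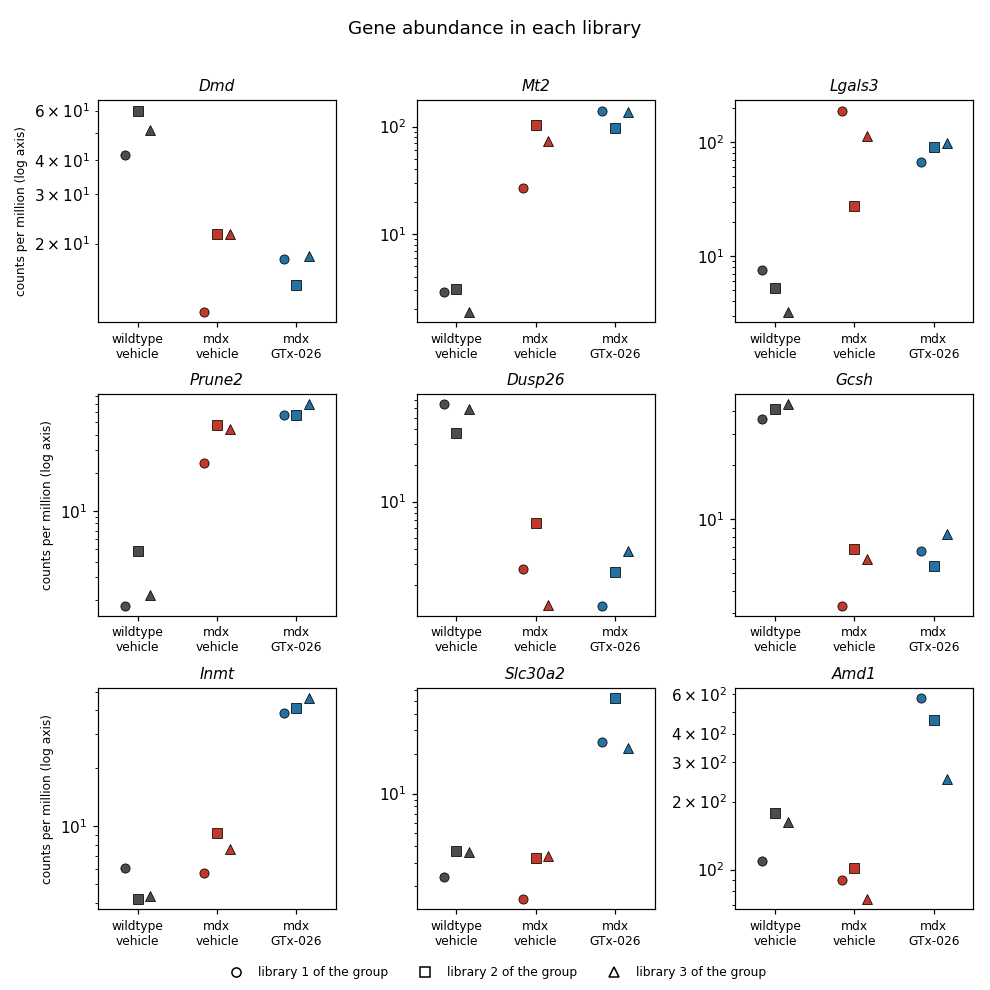
Expression of 9 genes in each of the 9 libraries, in CPM on a log axis, with one panel per gene and one column of points per group. Marker shapes give library 1, 2 or 3 of the group, numbers that pair nothing. Mt2, Lgals3 and Prune2 were higher and Dusp26, Gcsh and Dmd lower in mdx vehicle than in wildtype vehicle. Inmt was at 42.0 ± 3.99 CPM in mdx GTx-026 against 7.52 ± 1.77 CPM in mdx vehicle (SD, n = 3).

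By gene group, the macrophage and monocyte markers rose together in mdx vehicle. All 21 measured members were higher than in wildtype, with a median log2 fold change of 1.59 (camera adjusted p = 1.6e-10, and adjusted p = 0.79 with an estimated correlation). Lgals3 passed over all genes and 14 members rose when adjusted over the list alone, among them the complement genes C1qa, C1qb and C1qc, Cd14 and Gpnmb. Gpnmb was at 1.83 ± 0.498 CPM in wildtype and 159 ± 229 CPM in mdx vehicle (SD, n = 3). The median of the list lay at 2.68, 0.40 and 1.81 in mdx vehicle libraries 1 to 3, and without library 1 the list's log2 fold change was 1.03. Markers of lymphoid cells were also high in mdx vehicle library 1, where Cd52 was at 110 CPM against 2.09 and 5.84 CPM in the other mdx vehicle libraries. The lysosome genes were higher in 19 of 20 members with a median of 0.60 (adjusted p = 1.29e-07, and adjusted p = 0.79 with an estimated correlation), and of 0.37 without library 1. Of these 7 rose adjusted over the list alone, such as the cathepsins Ctsa, Ctsb and Ctsk. Of the extracellular matrix genes 27 of 29 were higher, with a median of 0.62 (adjusted p = 1.02e-06, and adjusted p = 0.82 with an estimated correlation). The list lay at 0.16, 0.325 and 1.44 in mdx vehicle libraries 1 to 3, and without library 3 its median was 0.25 (adjusted p = 0.0194). By limma 0 members passed over all genes or adjusted over the list alone. Among them the collagen Col3a1 was at 346 ± 220 CPM against 160 ± 23.8 CPM in wildtype (SD, n = 3).

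The neuromuscular junction and denervation genes were higher in 12 of 14 members (median 0.69; camera adjusted p = 3.79e-06, and adjusted p = 0.79 with an estimated correlation). Chrnb1 (chromosome 11, 69784036 to 69795966), the beta subunit of the muscle acetylcholine receptor, rose from 35.01 ± 4.42 to 75.5 ± 7.53 CPM (log2 fold change 1.11, adjusted p = 0.0295). The transcription factor Runx1 rose by 1.34 (adjusted p = 0.0386). Adjusted over the list alone 8 members rose, including Chrna1, Chrnd and Chrne, and the sodium channel Scn4a fell. Of the regeneration and developmental muscle genes 15 of 21 were higher (median 0.47, adjusted p = 0.00239, and adjusted p = 0.82 with an estimated correlation). Igf2 passed over all genes and 5 members adjusted over the list alone, among them the embryonic myosin light chain Myl4, the calcium pump regulator Sln and Ankrd1. Without mdx vehicle library 3 that list's median fell to 0.07 and its call was lost (adjusted p = 0.056). Of the immediate early genes 13 of 15 were higher (median 0.60, adjusted p = 0.000139, and adjusted p = 0.79 with an estimated correlation). Junb, Ier3 and Zfp36 passed adjusted over the list alone. The fibro-adipogenic progenitor markers (10 of 13 higher, median 0.41) passed as a list (adjusted p = 0.0168, and adjusted p = 0.82 with an estimated correlation). By limma 0 members passed over all genes, and Pdgfra and Cd55 rose adjusted over the list alone. The list lost its call without wildtype vehicle library 1 or mdx vehicle library 3 (highest adjusted p = 0.214, lowest median 0.13).

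Genes of mitochondrial metabolism were lower in mdx vehicle. All 35 nuclear-encoded genes of oxidative phosphorylation were below wildtype, with a median of −0.39 (camera adjusted p = 1.29e-07, and adjusted p = 0.82 with an estimated correlation). All 23 fatty acid oxidation genes (median −0.54, adjusted p = 3.06e-06) and all 18 tricarboxylic acid cycle genes (median −0.40, adjusted p = 1.95e-05) were lower too. Both had an adjusted p = 0.82 with an estimated correlation. In these 3 lists 0 members passed over all genes by limma, and adjusted over the list alone only Suclg2, a subunit of succinyl-CoA ligase, fell. Cox6a2, the muscle form of a cytochrome oxidase subunit, was at 744 ± 182 CPM in wildtype and 438 ± 116 CPM in mdx vehicle (SD, n = 3). The oxidative phosphorylation list lay at −0.83, 0.05 and −0.36 in mdx vehicle libraries 1 to 3. Library 1 was the one low in slow-fibre genes. Without library 1 the medians of the 3 lists were −0.155, −0.22 and −0.14, with a highest adjusted p of 0.038. The endothelial markers (13 of 14 lower, median −0.36, adjusted p = 0.0134) and the calcium handling genes (13 of 18 lower, median −0.215, adjusted p = 0.0323) were also lower. Each had an adjusted p = 0.836 with an estimated correlation. The calcium handling call was lost without wildtype vehicle library 1 or 3 or mdx vehicle library 1 (highest adjusted p = 0.323). The endothelial call was lost without these or mdx vehicle library 2 (0.21, with medians from −0.47 to −0.24).

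The remaining 22 lists tested did not pass in mdx vehicle against wildtype vehicle. The dystrophin-associated proteins had a median of 0.06 (camera adjusted p = 0.991), and adjusted over the list alone Dmd and the muscle nitric oxide synthase Nos1 fell while Sntb1 rose. The slow-fibre (−0.28, adjusted p = 0.382) and fast-fibre contractile genes (−0.27, adjusted p = 0.214), glycolysis (−0.19, adjusted p = 0.2) and ribosomal protein genes (−0.01, adjusted p = 0.766) did not pass. In the atrophy and autophagy list (−0.14, adjusted p = 0.499) Mt1 and Mt2, which bind metals, rose over all genes, and Ddit4 also adjusted over the list alone. The growth factor and activin list (−0.11, adjusted p = 0.2) did not pass. In it myostatin, Mstn, fell adjusted over the list alone, from 49.6 ± 14.1 to 21.8 ± 0.520 CPM (SD, n = 3). The androgen-responsive and polyamine list (0.03, adjusted p = 0.766) and cytokines (0.30, adjusted p = 0.244) did not pass, nor did interferon-stimulated genes (−0.09, adjusted p = 0.499) and satellite cell markers (−0.04, adjusted p = 0.499). Several of these values turned on mdx vehicle library 1. Without it the slow-fibre median was 0.95 (adjusted p = 0.109) and that of cytokines −0.08 (adjusted p = 0.455), while ribosomal proteins (−0.20, adjusted p = 0.000231) and satellite cell markers (0.14, adjusted p = 0.0355) passed. In 5 of these lists, dystrophin-associated proteins, atrophy, oxidative stress, satellite cell and erythroid, the signs of the median, the mean and the test were not all alike.

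**Figure D2:**
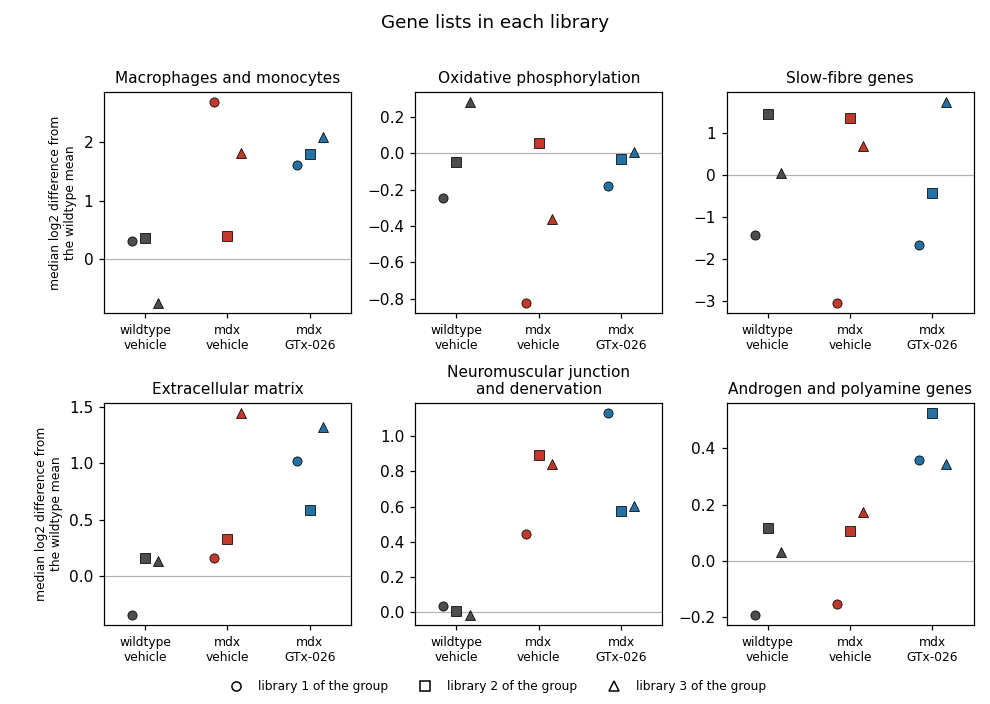
Median log2 difference from the wildtype mean in each of the 9 libraries for 6 gene lists. Each panel is a list, each column of points a group, and marker shapes give library 1, 2 or 3. The macrophage list lay at 2.68 and the slow-fibre list at −3.05 in mdx vehicle library 1. The androgen-responsive and polyamine list lay at 0.35 to 0.52 in the mdx GTx-026 libraries against −0.15 to 0.17 in the mdx vehicle libraries.

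In mdx GTx-026 against mdx vehicle, the comparison of treated with untreated mdx muscle, 2 genes rose and 0 fell of 15372 (limma with Benjamini-Hochberg adjustment). Inmt (chromosome 6, 55170627 to 55174990), an indolethylamine methyltransferase gene, rose from 7.52 ± 1.77 to 42.0 ± 3.99 CPM (SD, n = 3; log2 fold change 2.50, SE 0.22, adjusted p = 0.00997). Wildtype was at 4.84 ± 1.03 CPM. The zinc transporter gene Slc30a2 (chromosome 4, 134343046 to 134354484) rose from 2.76 ± 1.01 to 33.1 ± 17.0 CPM (3.53, SE 0.39, adjusted p = 0.0429), with 3.20 ± 0.735 CPM in wildtype. At an unadjusted p under 0.05 there were 296 genes higher and 185 lower, 3.13% of those tested, and 1045 genes (6.8%) had no overlap between groups where chance gives 10%. Slc30a2 lost its call without any of the 9 libraries (adjusted p 0.0726 to 0.208). Inmt lost its call without mdx vehicle library 3 or any mdx GTx-026 library (adjusted p up to 0.126). The count by limma was 0 in these 4 fits, with 849, 442, 432 and 406 genes at an unadjusted p under 0.05, and 1 in the other 5.

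The androgen-responsive and polyamine genes rose with GTx-026 as a list. Of 22 members 15 were higher, with a median log2 fold change of 0.15 (camera adjusted p = 6.59e-05, and adjusted p = 0.613 with an estimated correlation). The list passed without any single library, but without mdx vehicle library 1 its median was 0.06 (adjusted p = 0.0156), and with the deposited scaling it was 0.08. Over all genes 0 members passed by limma, and adjusted over the list alone 4 rose, Odc1, Amd1, Amd2 and Tiparp. Amd1 (chromosome 10, 40287458 to 40302188), S-adenosylmethionine decarboxylase of polyamine synthesis, was at 88.4 ± 13.8 CPM in mdx vehicle and 429 ± 164 CPM with GTx-026 (SD, n = 3; 2.21, SE 0.30, adjusted p = 0.13). In wildtype it was at 150 ± 35.7 CPM. Its retrocopy Amd2 was at 40.8 ± 9.79 and 182 ± 68.9 CPM, but Amd1 shared 76.7% of its words with Amd2, so the pair cannot be separated. Both are members of the list, so the list test and the count of 4 may take the same reads as 2 members. Odc1 (chromosome 12, 17544808 to 17551502), ornithine decarboxylase, was at 93.2 ± 11.96 and 163 ± 15.1 CPM (0.81, adjusted p = 0.75). Tiparp was at 15.8 ± 1.26 and 32.3 ± 6.84 CPM (1.01, adjusted p = 0.444). The list of sex-linked transcripts fell (median −0.27, adjusted p = 0.0245, and adjusted p = 0.816 with an estimated correlation), with Kdm5d adjusted over the list alone. It was lost without mdx vehicle library 1 or 2 or mdx GTx-026 library 1 or 2 (highest adjusted p = 0.257, with medians from −0.42 to −0.13). Xist was between 1.92 and 2.16 CPM and the Y-linked Ddx3y between 41.4 and 52.2 CPM in the group means.

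The mitochondrial lists were higher with GTx-026 than in mdx vehicle. All 35 oxidative phosphorylation genes had a positive log2 fold change (median 0.295, camera adjusted p = 2.94e-07). So had all 18 tricarboxylic acid cycle genes (median 0.30, adjusted p = 0.00031) and 20 of 23 fatty acid oxidation genes (median 0.29, adjusted p = 0.0245). Each had an adjusted p = 0.816 with an estimated correlation, and 0 members passed by limma over all genes or adjusted over the list alone. These calls rested on mdx vehicle library 1, in which the slow-fibre list was also lowest. Without it the medians were 0.06, 0.02 and −0.12 and the adjusted p 0.348, 0.736 and 0.0964. The fatty acid oxidation call was lost also without mdx GTx-026 library 2 or 3 (highest adjusted p = 0.394). The dystrophin-associated proteins (15 of 18 higher, median 0.21, adjusted p = 0.0024) passed too, with an adjusted p = 0.816 with an estimated correlation. They lost the call without mdx vehicle library 1 (median 0.06, adjusted p = 0.556).

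Extracellular matrix genes (23 of 29 higher, median 0.43, adjusted p = 0.000721), fibro-adipogenic progenitor markers (11 of 13, median 0.41, adjusted p = 0.00154) and smooth muscle markers (10 of 10, median 0.30, adjusted p = 0.0206) were higher with GTx-026. Each had an adjusted p = 0.816 with an estimated correlation. The extracellular matrix and smooth muscle calls were lost without mdx vehicle library 1 or 2 or mdx GTx-026 library 3 (highest adjusted p = 0.448 and 0.527, lowest medians 0.20 and 0.06). The progenitor markers lost theirs without mdx GTx-026 library 3 (adjusted p = 0.0648), and their median was 0.22 without mdx vehicle library 1. With array quality weights, chosen after the data were seen, the tests of the extracellular matrix and smooth muscle lists turned direction (medians 0.06 and −0.02, adjusted p = 0.597 and 0.991). Gsn, the actin-severing gelsolin, was at 681 ± 342 and 1326 ± 268 CPM (SD, n = 3). The oxidative stress list (14 of 19 higher, median 0.25, adjusted p = 0.000153, and adjusted p = 0.613 with an estimated correlation) passed as well, with medians of 0.16 to 0.26 when 1 library was left out. Adjusted over the list alone 1 member rose, the glutathione peroxidase Gpx3, at 129 ± 11.5 and 239 ± 45.7 CPM. The immediate early genes were lower in 12 of 15 members (median −0.28, adjusted p = 0.0327, and adjusted p = 0.816 with an estimated correlation). They lost the call without mdx vehicle library 2 or mdx GTx-026 library 3 (highest adjusted p = 0.982, with a median of 0.02).

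The erythroid markers, mainly globins of red blood cells, were higher in 9 of 9 members with GTx-026 (median 0.93, adjusted p = 0.000153, and adjusted p = 0.816 with an estimated correlation). Without mdx vehicle library 1 the median was 0.37 (adjusted p = 0.0169). The beta-globin genes of this list are close copies, and their shares differed between libraries of the same group. Hbb-b1 made up 13.9%, 12.3% and 13.8% of Hbb-b1 plus Hbb-bs in the wildtype vehicle libraries. Its share was 94.8%, 17.7% and 64.5% in the mdx vehicle libraries and 94.3%, 59.6% and 63.4% in the mdx GTx-026 libraries. The macrophage and monocyte markers (median 0.04, adjusted p = 0.253), lysosome (−0.02, adjusted p = 0.776) and neuromuscular junction lists (0.08, adjusted p = 0.253) did not pass with GTx-026. Nor did the regeneration list (0.16, adjusted p = 0.228), the slow-fibre contractile genes (0.29, adjusted p = 0.371) or the fast-fibre contractile genes (0.02, adjusted p = 0.622). Without mdx vehicle library 1 the log2 fold change of the macrophage and monocyte markers was 0.60 (adjusted p = 4.27e-06) and that of the slow-fibre contractile genes −1.22 (adjusted p = 0.00513). The lysosome list then passed as well (0.19, adjusted p = 0.0418), as did the interferon-stimulated genes (0.39, adjusted p = 0.0156), cytokines (0.29, adjusted p = 0.0458) and ribosomal proteins (0.12, adjusted p = 0.00194). The regeneration list turned to −0.175 (adjusted p = 0.0964).

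In mdx GTx-026 against wildtype vehicle, which asks what remained of the mdx difference under treatment, 167 genes rose and 64 fell (limma with Benjamini-Hochberg adjustment). Mt2 rose to 125 ± 24.1 CPM (SD, n = 3; log2 fold change 5.56, adjusted p = 0.00083), Prune2 to 61.0 CPM (4.48, adjusted p = 0.00115). Mt1 rose to 149 ± 7.76 CPM (4.13, adjusted p = 0.00473). Dusp26 fell most (−4.43, adjusted p = 0.00728). The phosphatase inhibitor gene Ppp1r1a (chromosome 15, 103530279 to 103538027) fell from 89.9 ± 6.99 to 6.50 ± 4.58 CPM (−4.18, adjusted p = 0.0109), and the cadherin gene Cdh4 (chromosome 2, 179442423 to 179899377) from 32.4 ± 9.98 to 3.67 ± 3.01 CPM (−3.37, adjusted p = 0.0279). Ppp1r1a lost its call without wildtype vehicle library 3 (adjusted p = 0.0515), and Cdh4 without any of the wildtype vehicle libraries or mdx GTx-026 library 2 or 3 (adjusted p up to 0.11). The calcium-sensing receptor gene Casr fell to 11.3 ± 1.99 from 37.5 ± 5.60 CPM (−1.73, adjusted p = 0.00524), with 27.6 ± 5.51 CPM in mdx vehicle. At an unadjusted p under 0.05 there were 1949 genes, and 3193 genes (20.8%) had no overlap between groups where chance gives 10%. Without wildtype vehicle libraries 2 and 3 the count was 66 and 43. Without mdx vehicle library 1 it was 377, and without mdx GTx-026 libraries 1, 2 and 3 it was 61, 79 and 68.

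The lists higher in mdx vehicle were also higher in mdx GTx-026 against wildtype vehicle. All 21 macrophage markers were higher (median 1.82, camera adjusted p = 1.34e-12, and adjusted p = 0.521 with an estimated correlation). Lgals3 and the complement gene C1qc (2.07) rose over all genes and 15 members adjusted over the list alone. All 29 extracellular matrix genes were higher (median 0.98, adjusted p = 3.51e-12, and adjusted p = 0.607 with an estimated correlation). Of these 0 passed by limma over all genes and 19 rose adjusted over the list alone, including Col1a1, Col3a1, Fn1 and Lox. The neuromuscular junction list was higher in 12 of 14 members (median 0.70, adjusted p = 2.17e-07, and adjusted p = 0.521 with an estimated correlation), with medians of 0.45 to 0.87 when 1 library was left out. In it Chrna1 (1.34), Chrnb1 (1.10), the junction kinase Musk (1.76) and Runx1 (1.59) rose over all genes, and 9 rose and 1 fell adjusted over the list alone. The lysosome list (20 of 20 higher, median 0.53, adjusted p = 2.17e-07) and the fibro-adipogenic progenitor list (13 of 13, median 0.76, adjusted p = 3.08e-06) were higher too. Each had an adjusted p = 0.521 with an estimated correlation, and 7 and 4 members rose adjusted over the list alone. Of the regeneration genes 15 of 21 were higher (median 0.74, adjusted p = 0.000206, and adjusted p = 0.607 with an estimated correlation), with medians of 0.44 to 0.97 when 1 library was left out. Myl4 (2.86), Igf2 (2.66) and Ankrd1 (2.45) rose, while the myosin-binding protein gene Mybph fell to 277 ± 137 from 905 ± 217 CPM (SD, n = 3; −1.83).

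The androgen-responsive and polyamine list, which did not pass in mdx vehicle, was higher in mdx GTx-026 than in wildtype. Of 22 members 16 were higher (median 0.46, camera adjusted p = 0.000593, and adjusted p = 0.521 with an estimated correlation). Fkbp5, a steroid-receptor chaperone gene, rose from 10.9 ± 0.932 to 61.5 ± 13.04 CPM (SD, n = 3; 2.47, adjusted p = 0.0279), with 31.4 ± 22.4 CPM in mdx vehicle. Odc1 (1.13), Tiparp (1.04) and Amd1 (1.47) also rose over all genes, and 5 rose and 1 fell adjusted over the list alone. Amd1 and Amd2, which cannot be separated, are both members of this list.

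In the oxidative stress list Srxn1 (0.81) and Gpx1 (1.38) rose (15 of 19 higher, median 0.215, camera adjusted p = 0.0335, and adjusted p = 0.607 with an estimated correlation). Among the cytokines Cxcl14 (1.86) rose (9 of 14 higher, median 0.35, adjusted p = 0.0389, and adjusted p = 0.607 with an estimated correlation). Among the immediate early genes Ier3 (1.04) rose (11 of 15 higher, median 0.34, adjusted p = 0.0335, and adjusted p = 0.747 with an estimated correlation). Among the erythroid markers Hbb-b1 (3.67) and Hbb-b2 (4.11) rose (6 of 9 higher, median 0.63, adjusted p = 0.0335, and adjusted p = 0.811 with an estimated correlation). The shares of Hbb-b1 and Hbb-b2 in the beta-globins varied between the mdx libraries. The oxidative stress list lost its call without wildtype vehicle library 2 or 3, mdx vehicle library 1 or mdx GTx-026 library 3 (highest adjusted p = 0.143). Cytokines lost theirs without wildtype vehicle library 1 or 3, mdx vehicle library 1 or 3 or mdx GTx-026 library 3 (0.203). The immediate early genes lost theirs without wildtype vehicle library 2 or mdx GTx-026 library 1 or 2 (0.122, lowest median 0.20). The erythroid markers lost theirs without wildtype vehicle library 1 or 2, mdx vehicle library 1 or mdx GTx-026 library 2 (0.235, lowest median 0.29). The fatty acid oxidation genes were lower (21 of 23, median −0.32, adjusted p = 0.00358, and adjusted p = 0.917 with an estimated correlation). That call was lost without mdx GTx-026 library 1 (adjusted p = 0.0833), and medians ran from −0.40 to −0.20 when 1 library was left out. Oxidative phosphorylation (−0.07, adjusted p = 0.15) and the tricarboxylic acid cycle (−0.10, adjusted p = 0.143) did not pass.

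Whether GTx-026 reversed the mdx changes was examined on the genes and on all log2 fold changes. Of the 51 genes called in mdx vehicle, 48 were also called in mdx GTx-026 against wildtype vehicle, and all 51 had the same sign there. Of these 31 rose and 17 fell. Their median size of log2 fold change was 1.69 in mdx vehicle and 2.04 in mdx GTx-026, and 37 of them, Mt2 and Prune2 included, were farther from wildtype with GTx-026 than without. Both comparisons use the same wildtype libraries, of which 3 are too few to divide, so part of this overlap may come from the shared controls. By limma 0 genes were called in both mdx vehicle against wildtype and mdx GTx-026 against mdx vehicle, in either the opposite or the same direction. In 100 simulations of unchanged groups a mean of 88.2 genes, with a range of 0 to 3010, were called in both with opposite sign. Many genes can thus be called together where nothing changed, which limits every count of called genes. At an unadjusted p under 0.05 in both, 88 genes had the opposite and 59 the same sign. The mdx vehicle libraries enter both comparisons with opposite sign, which by itself favours opposite signs, so this count shows no reversal. Across genes, which are not independent replicates, the covariance of the mdx change and the GTx-026 change was −0.0346. In comparison, 100 simulations of unchanged groups sharing the mdx vehicle libraries gave a mean of −0.0875 and a range of −0.327 to 0.0159, a difference of 0.0528. It was −0.117 and −0.0806 without mdx vehicle library 2 or 3 and −0.0761 without a filter. The correlation was −0.271 beside a simulated −0.565 (−0.992 to 0.202). The covariance of the changes against wildtype in mdx vehicle and in mdx GTx-026 was 0.161, inside the simulated range of −0.0314 to 0.479 (mean 0.0584).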

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

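The tests of lymphoid and slow-fibre RNA, of the mitochondrial lists, of the Tdg pair and of the beta-globin shares were chosen only after the result was seen, with their thresholds, and those of depth, of linkage and of other splits of the libraries before.

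The comparisons above leave out genes listed at 0 in a whole group, and 116 gene symbols were listed at 0 in all 3 wildtype libraries and above 0 in all 6 mdx libraries. The smallest scaled value above 0 was 10 and zeros always covered a whole group, so 0 need not mean absence, and no fold is given. Among these genes, named after their values were seen, was Tnnt2, cardiac and embryonic troponin T, at a mean of 16.5 CPM in mdx vehicle and 26.7 CPM in mdx GTx-026. The cell-cycle inhibitor Cdkn2a was at 13.5 and 12.4 CPM and the macrophage receptor Trem2 at 15.7 and 9.17 CPM. Trem2 was at 32.3, 2.23 and 12.4 CPM in mdx vehicle libraries 1 to 3. The CPM values of this paragraph are without the rescaling of the others, which would lower mdx vehicle library 1 most (factor 1.30). Chrng, the fetal subunit of the acetylcholine receptor, was at 2.61 and 2.77 CPM, the muscle differentiation regulator Mdfi at 4.5 and 5.75 CPM and the protease inhibitor Timp1 at 2.86 and 4.23 CPM. In the opposite direction 19 symbols were listed in wildtype alone, among them Efcab6 at 12.4 CPM, 26 were listed in mdx GTx-026 alone and 50 in mdx vehicle alone.

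The mdx vehicle library 1 differed from the other 2 mdx vehicle libraries, with 986 genes at least 2-fold above and 766 at least 2-fold below their mean. Lower depth is argued against, because over 2470 genes of at least 50 CPM its median correlation with its group was still 0.853, below the 0.896 of the lowest other library. Leukocyte RNA from lymphoid tissue in the piece sampled is a candidate source of the excess, since the 14 measured of 56 lymphoid markers were all higher, by a median log2 of 3.41 (quartiles 2.32 to 3.80; Ccl21a at 52.1 CPM, Cd52 at 110 CPM), beyond the 1.75 of the macrophage markers; 2 of the 14 stand in another list, and Cd52 was also at 37.8 CPM in wildtype vehicle library 1 and 26.2 CPM in mdx GTx-026 library 2. A piece with fewer slow fibres may account for some of the low part, since the slow-fibre list lay at −4.18 from the other mdx vehicle libraries. The idea came from this same list, so the value is no separate support, and its part in the 766 low genes was not tested. The leukocyte and slow-fibre sources both stay open, together with a real difference between mdx animals, which was not tested.

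The mitochondrial lists were lower in mdx vehicle and higher with GTx-026, and mdx vehicle library 1 entered both differences. For the rise with GTx-026 that library alone may be the cause, because without it the lowest adjusted p of the 3 lists was 0.0964 and the median of the fatty acid oxidation list turned negative. For the fall in mdx vehicle this cannot be decided. Without that library the highest adjusted p of the 3 lists was 0.038, but at a preset correlation, and the medians of −0.155, −0.217 and −0.142 lay inside the range of the single wildtype libraries in all lists but fatty acid oxidation (lowest −0.245, −0.177 and −0.266). An effect of the mutation or of GTx-026 on mitochondrial genes stays open.

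Some differences between mdx and wildtype libraries may come from genetic background rather than from Dmd, although all carry the same strain label. For the 48 genes changed in both mdx groups, 26.7% of the 45 with a position had another of them within 5 Mb, where random sets gave a median of 22.2% and a 95th percentile of 35.6%, so a linked segment was neither shown nor excluded. For Tdg and its copy Gm9855 the sum of the pair differed by only −0.253 in mdx vehicle and −0.158 in mdx GTx-026. Reads moving between the copies, as a sequence variant could cause, would give such a sum and may be the reason. Tdg itself shared only 15.8% of its words with Gm9855, so how much of its fall such reads could cover is not known. For the beta-globins, the share of Hbb-b1 in Hbb-b1 plus Hbb-bs ranged over 77.1 percentage points among the 6 mdx libraries and over 1.54 among wildtype, and that of Hbb-b2 in Hbb-b2 plus Hbb-bt over 71.5 and 1.03 (Spearman correlation of both shares 0.771 over the 6 mdx libraries, with no test), which is consistent with different beta-globin haplotypes among the mdx mice. Genotypes were not measured, the globin genes are close copies that can trade reads, and an effect of GTx-026 on red blood cells stays open.

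The 6 libraries of a comparison can be divided in 10 ways, too few for a share under 0.05. For mdx vehicle against wildtype vehicle the real division gave 51 genes and the highest other 1, for mdx GTx-026 against mdx vehicle 2 and 0, and for mdx GTx-026 against wildtype vehicle 231 and 0, so 1 division of 10 gave as many genes in each. For the gene lists the real divisions gave 12, 12 and 12 and the highest others 22, 23 and 17, and 7, 9 and 6 of the 10 divisions gave as many. List calls of this number were therefore not particular to the real divisions. Each other division sets 2 libraries of a group beside 1 of the other group. It thus keeps part of the group difference and takes the rest into its spread. These counts, of genes or of lists, cannot separate the groups from another structure of the libraries that the lists may follow.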

How the results depend on the processing

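Array quality weights, the highest record of each gene and mean-variance observation weights were tests chosen only after the result was seen. For mdx vehicle against wildtype vehicle the count of 51 genes became 349 without a filter, 306 with array quality weights, 6 with the compared groups alone and 101 at an adjusted p under 0.1, and 5 to 85 when 1 library was left out. All 51 were among the 349 and the 306, and 5 among the 6. For mdx GTx-026 against mdx vehicle the count of 2 became 4 with the deposited scaling, 98 without a filter, 4 with array quality weights, 1 with observation weights, 1 with the compared groups alone, and 0 to 1 without 1 library (limma, with 406 to 849 genes at an unadjusted p under 0.05 where it was 0). For mdx GTx-026 against wildtype vehicle the count of 231 became 538 without a filter, 858 with array quality weights, 414 with the compared groups alone and 429 at an adjusted p under 0.1, and 43 to 377 without 1 library. Genes changed by mdx and reversed by GTx-026 numbered 0, and 52 without a filter. Among the symbols that the filter leaves out, 50 were listed in mdx vehicle alone and 1 was at 0 in mdx vehicle alone. Such a pattern counts as a reversal wherever it is called, and 0 need not mean absence, so the 52 are not read as a reversal. Without a filter 188 of 349, 86 of 98 and 170 of 538 genes were listed at 0 in a group, so that part of the counts comes from genes that the filter leaves out. For the rest and for the other settings the cause was not tested.

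Of the 12 gene lists called in each comparison, 0 held with camera's estimated correlation (1, 2 and 1 lists at an unadjusted p under 0.05) and 0 with fry's directional test. Over all 34 lists fry's mixed test called 7 in mdx vehicle against wildtype vehicle, 11 in mdx GTx-026 against wildtype vehicle and 1 in mdx GTx-026 against mdx vehicle. Of these 7 only the neuromuscular junction and regeneration lists were among the 12. The 11 included the dystrophin-associated proteins, which camera did not call (adjusted p = 0.0706). In mdx GTx-026 against mdx vehicle camera with array quality weights called 6. Leaving out 1 library gave 10 to 15, 11 to 21 (21 without mdx vehicle library 3) and 9 to 15 lists. With GTx-026 against mdx vehicle, array quality weights turned the direction of the test for the extracellular matrix and fibrosis list (median 0.0604, adjusted p = 0.597) and for smooth muscle and pericyte markers (median −0.0236, adjusted p = 0.991). Leaving out 1 library gave the fatty acid oxidation list medians of −0.123 to 0.527. With the deposited scaling the median log2 fold change of all genes was 0.182, −0.0557 and 0.112 in the 3 comparisons, beside 0.009, 0.00811 and 0.00296, the share of calls that rose went from 62.7% to 75.9% in mdx vehicle and from 72.3% to 81.3% in mdx GTx-026 against wildtype vehicle, and no called list turned its sign. In mdx vehicle against wildtype vehicle the medians shrank to −0.0401 for calcium handling, −0.211 for oxidative phosphorylation, −0.222 for the tricarboxylic acid cycle and −0.19 for endothelial markers. In mdx GTx-026 against wildtype vehicle the fatty acid oxidation median shrank to −0.21, and the deposited scaling cost 4 lists their call: cytokines and chemokines (adjusted p = 0.0621), oxidative stress response (0.0759), immediate early genes (0.0515) and erythroid markers (0.0621). Over all pairs of named gene and setting with all libraries, 287 were the same, 31 weaker, 12 stronger and 0 reversed, and when 1 library was left out 170 were the same, 125 weaker, 2 stronger and 0 reversed. The count-model alternatives were not run, because the table holds scaled values and reads recovered from them were not accepted as counts. How the calls would fare under a count model is therefore not known. No paired analysis was possible because the labels number the libraries 1 to 9 with no number shared between groups.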

Other observations

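The genes and lists of this part were chosen after their values were seen, and no test here was fixed before. Some genes outside the lists were far from wildtype in both mdx groups. Ostn, which encodes the muscle-secreted peptide osteocrin, was at 68.4 ± 35.4 CPM in wildtype vehicle, 10.2 ± 4.74 CPM in mdx vehicle and 7.21 ± 3.20 CPM in mdx GTx-026 (SD, n = 3), and it fell in mdx GTx-026 against wildtype vehicle (log2 fold change −3.16, SE 0.54, limma with Benjamini-Hochberg adjusted p = 0.025). The serine protease gene Htra4 fell in both, by 2.68 and 3.11 on the log2 scale, from 10.1 ± 2.26 CPM. The smallest adjusted p in mdx vehicle, 0.000542, was that of the predicted gene LOC102641654, at 3.62 ± 0.369 CPM in wildtype and 24.9 ± 4.97 CPM in mdx vehicle.

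Some genes were farther from wildtype in mdx GTx-026 than in mdx vehicle. Tfcp2l1, a transcription factor gene, was at 5.88 ± 0.147, 9.83 ± 2.97 and 29.0 ± 6.49 CPM in wildtype vehicle, mdx vehicle and mdx GTx-026, and Cbr2, a carbonyl reductase gene, at 12.6 ± 3.01, 15.7 ± 4.35 and 50.5 ± 17.0 CPM (SD, n = 3). Both rose in mdx GTx-026 against wildtype vehicle (adjusted p = 0.00481 and 0.0146) and did not pass against mdx vehicle (adjusted p = 0.214 and 0.384); Cbr2 shared 12.1% of its words with Gm11771. The scavenger receptor gene Stab2 was at 9.00 ± 1.06, 8.39 ± 1.89 and 18.8 ± 2.62 CPM. The cholesterol transporter gene Npc1 was at 37.8 ± 2.57, 29.1 ± 2.27 and 52.2 ± 3.41 CPM, and did not pass against mdx vehicle (adjusted p = 0.184).

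The adipocyte markers followed no group. Their median log2 difference from the wildtype mean was 2.69, −1.22 and −1.50 in the wildtype vehicle libraries, −0.88, −1.37 and 1.97 in the mdx vehicle libraries and −0.36, 1.44 and 0.13 in the mdx GTx-026 libraries. Of the p-values that the authors deposited, 2790 records (6.01%) had an unadjusted p under 0.05 for wildtype against mdx vehicle, 4324 (9.32%) for wildtype against mdx GTx-026 and 902 (1.94%) for mdx vehicle against mdx GTx-026. After Benjamini-Hochberg adjustment of these deposited p-values 0 records passed, with lowest values of 0.127, 0.0654 and 1, where limma on the summed genes called 51, 231 and 2.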
